A study of Mus musculus with 6 samples.

How the data were processed

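Polyadenylated RNA of MuTuDC1940 cells was sequenced from stranded libraries (NEBNext Ultra II Directional), per the labels' protocols, in 3 untreated samples and 3 samples given poly(I:C) at 5 µg/ml for 18 hours. The submitters' processing notes name bcl2fastq 2.20.0.422, kallisto 0.42.4 and the build GRCm38, with no role or order for the tools. The deposited table is named as FPKM, but each value column used sums to 1000000, as TPM (transcript abundance relative to a fixed total) does and FPKM does not, so the deposited values were taken as TPM per RefSeq transcript. TPM keeps no record of sequencing depth, so the depth of each library is unknown and no count test or counting interval was used. Whether the authors' quantification used strand is not given in the sources used here, so reads of antisense partners may be shared between genes. An entry of 0 was read only as listed at 0.

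The header of the table holds 5 sample names for 6 value columns, with an empty cell after NT01, so the names after it may stand 1 column too far to the right. The columns headed NT01, NT02, PolyIC01 and PolyIC02 belong to the same group under either reading and were used, 2 per group. The remaining 2 columns of per-sample values were not used in any step. The choice to leave them out rests on the header alone but was made after the table had been opened and the values of all 6 columns had been looked at. In that look the column headed NT03 resembled the columns headed PolyIC01 and PolyIC02, which bears on how the header should be read; it was not tested further. Replicate numbers other than that of NT01 are not settled, and the libraries are called by the headings of their columns.

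Of 107384 transcripts, 86722 (80.8%) matched a gene symbol of the RefSeq gene table (GRCm38.p6) by accession without version, and they held 91.8% to 92.2% of each library's TPM. Their TPM were summed per gene, giving 32903 symbols, and the 20662 unmatched transcripts, mostly predicted ones, were left out. Genes with a mean of at least 0.5 TPM over the 4 libraries (12520) were tested. A gene low in untreated cells can reach this limit through the treated libraries alone, which favours rises among the low genes tested. A fold change is on the log2(TPM + 1) scale, which understates the change of genes with low values; counts of genes that moved at least 2-fold or 8-fold are made on that scale, so low genes with larger ratios of TPM may be missing from them. A fold given for a single gene is a ratio of mean TPM.

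The groups were compared with limma 3.58.1 in R 4.3.3 with an intensity trend and robust moderation, and p was adjusted over all tested genes by the Benjamini-Hochberg method. A gene rose or fell where its adjusted p was under 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. With 2 libraries against 2 the fit has 2 residual degrees of freedom, and limma borrows spread across genes. The fit was tested on simulated data made from the untreated means of the 12520 genes and the trend of their spread with expression, with changes given only to genes whose untreated log2(TPM + 1) was at least 2, so it says little of lower genes. Of the 12143 simulated genes that reached the expression limit, 100% of the 50 changed genes of each size (log2 changes of 0.5, 1, 2 and 3) were recovered, with 11 false calls (5.2% of calls), and data with no changed gene gave 0 calls, with 5.3% of genes under an unadjusted p of 0.05. That simulation gives each gene independent noise with a spread exactly on the trend. It says nothing of noise shared between genes or of genes that vary more than the trend, and spread is then easily borrowed across genes. The recovery and false calls therefore do not measure how the fit does on the real libraries.

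A set of 27 gene lists with 448 genes was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Each list with at least 3 tested members was compared with all other tested genes by camera, with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over 22 lists. No list passed the estimated version, which has little power with 2 residual degrees of freedom. Some estimates lay far above the preset, such as 0.367 for interferon-stimulated antiviral genes, 0.390 for interferon-inducible GTPases and 0.550 for NF-kB. Others lay near it or under 0, such as 0.014 for MHC class I and -0.023 for proliferation. Where the true correlation exceeds the preset, the p-value of the preset version is too small. The list of mitochondrial-encoded genes has no member among the matched transcripts and gave no result. The rule names every tested Apol gene; up to 2 passing members per list with the largest change; the 6 largest rises and falls among passing genes with a mean of at least 1 TPM, no overlap between groups and a standard symbol; and a few regulators and receptors set beforehand, among them Irf8, Batf3, Irf7, Tlr3 and Clec9a. Some genes that the rule selects are left out of the text. Other genes named are said to have been chosen after their values were seen.

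The design fixed beforehand assumed FPKM and 6 libraries. It was applied to TPM and 4 libraries, with the same limits, and the replicate block could not be fitted. The alternatives were pseudocounts of 0.1 and 0.01, no expression limit or one of 2 TPM, rescaling of the named genes to a sum of 1000000, median-of-ratios and quantile scaling, limma without trend or robust moderation, values per transcript, leaving out each library in turn, an adjusted p under 0.01, a 2-fold limit and camera with an estimated correlation. No scaling moved the median log2 fold change of all genes by more than 0.1, and the share of risen genes among those that passed was 46.7%, 51.1% with median-of-ratios and 43.1% with quantile scaling.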

Results

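RNA sequencing of polyadenylated RNA was used to find which genes rise when MuTuDC1940 cells meet poly(I:C). MuTuDC1940 is a mouse dendritic cell line with features of type 1 conventional dendritic cells (cDC1), the subset specialised in presenting engulfed antigen on MHC class I. Poly(I:C) is a synthetic double-stranded RNA that stands in for viral RNA, and it was given at 5 µg/ml for 18 hours. The series holds 3 untreated and 3 treated samples, of which 2 libraries per group are compared here because the header of the deposited table leaves the group of the other 2 columns open. Each library is a set of values in TPM (transcript abundance relative to a fixed total) summing to 1000000, so its sequencing depth is unknown and no counting interval can be given. In the untreated libraries headed NT01 and NT02, 11346 and 11207 genes reached 1 TPM, and in the treated libraries headed PolyIC01 and PolyIC02, 11584 and 11504 genes did so. Libraries of the same group were close to each other: across the 12520 genes tested, Pearson's r of log2(TPM + 1) was 0.997 for both same-group pairs and between 0.956 and 0.959 for pairs of an untreated and a treated library. These correlations are across genes, which are not independent replicates.

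Poly(I:C) changed a large part of the transcriptome, and the strongest changes were rises. The chemokine gene Ccl5, whose product attracts T cells, rose most on the log2(TPM + 1) scale, from 5.31 ± 0.129 to 865 ± 8.67 TPM (SD, n = 2 libraries per group throughout), a log2 fold change of 7.10 (SE 0.033). It was followed by Slfn1 of the Schlafen family (6.55), Acod1, which encodes the enzyme that makes itaconate (5.73), Ifit3 (5.47), Ifitm1 (5.17) and the transcription factor gene Irf7 (5.03). Of these genes, Slfn1 (380-fold) and Irf7 (165-fold) come before Ccl5 (163-fold) by the ratio of mean TPM. Among the deepest falls were those of Bdh2 (24.3 ± 0.455 to 2.77 ± 0.140 TPM, log2 fold change -2.75), Cyp8b1 (-2.66), Dmpk (-2.57) and the gut-homing integrin gene Itgb7 (-2.52). The small nucleolar RNA gene Snora23 was next: it was at 7.85 and 2.73 TPM in the untreated libraries and listed at 0 in both treated ones.

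Of 12520 genes tested with limma, 712 rose and 345 fell at least 2-fold on the log2(TPM + 1) scale at an adjusted p under 0.05 (Benjamini-Hochberg), and 62 of the risen genes passed 8-fold. Without a limit on the size of the change, 3556 genes rose and 4062 fell, so most of the genes that passed (6561) moved by less than 2-fold. The untreated and treated values did not overlap for 10185 genes (81.3%), where chance gives 33.3% with 2 libraries against 2. The labels do not say that the samples of a group were separate cultures, so these p-values measure only the spread between these libraries, which may be technical. The call for Snora23 (adjusted p = 0.0122 in limma) was lost without either treated library (adjusted p = 0.173 without PolyIC01 and 0.163 without PolyIC02).

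**Figure D1:**
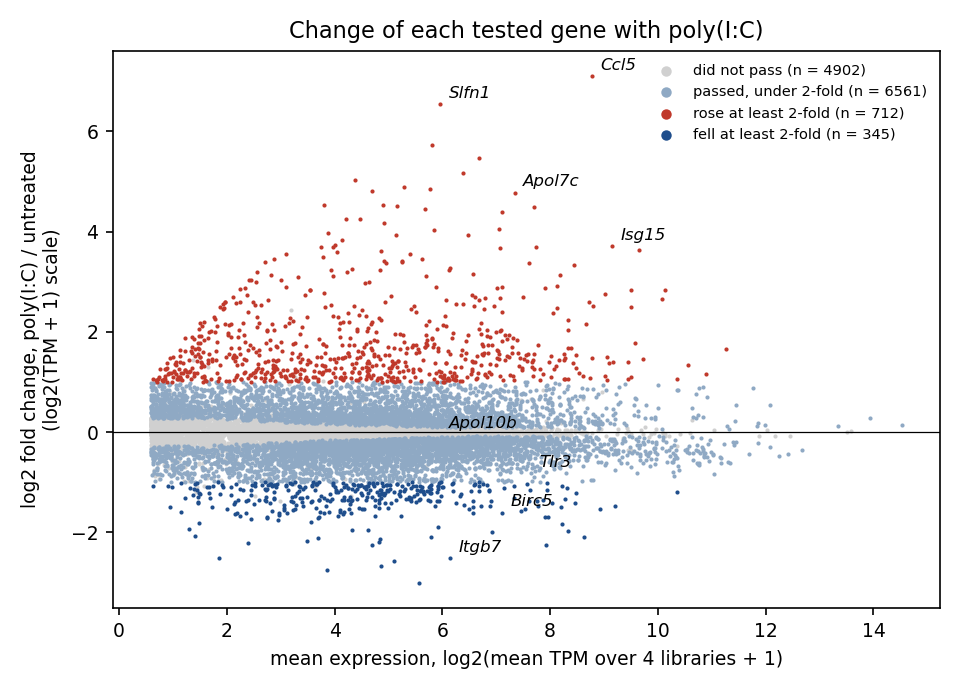
Log2 fold change of each of the 12520 tested genes (vertical axis, log2(TPM + 1) scale) against its mean expression over the 4 libraries (horizontal axis, log2). Each point is a gene; red points are the 712 genes that rose at least 2-fold, dark blue the 345 that fell at least 2-fold, light blue the 6561 that passed with a smaller change and grey the 4902 that did not pass. Apol7c lies among the largest rises and Apol10b near 0.

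The title of the series names APOL7C, a member of the apolipoprotein L family described there as forming pores, and its gene was among the most strongly induced. Apol7c rose from 10.5 ± 0.551 to 313 ± 6.71 TPM, 30.0-fold, with a log2 fold change of 4.78 (SE 0.046, adjusted p = 3.66e-07 in limma), the 10th largest rise on this scale of all tested genes that passed. Both treated libraries lay above both untreated ones, although an exact permutation test on 2 against 2 libraries cannot go below p = 0.333 (two-sided) and so adds nothing here. The gene lies on chromosome 15 at 77524852 to 77533335 (GRCm38, RefSeq annotation), inside a cluster of 12 Apol genes that spans 77045050 to 77757062. The curated RefSeq transcript went from 0.613 and 3.48 TPM to 180 and 169 TPM, and the predicted one from 10.2 and 6.59 TPM to 138 and 139 TPM. How the values of the untreated libraries divide between these transcripts is uncertain, since the curated transcript held 5.65% of the gene's TPM in NT01 and 34.5% in NT02.

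Of the 5 Apol genes that could be tested, 4 rose. Apol9b went from 0.346 ± 0.0472 to 14.7 ± 0.512 TPM (log2 fold change 3.54), Apol9a from 0.149 ± 0.0101 to 7.34 ± 0.307 TPM (2.86), and Apol7b from 0.858 ± 0.216 to 2.95 ± 0.0976 TPM (1.09, adjusted p = 0.000532 in limma). Apol10b was the most abundant member in untreated cells and showed no detectable difference, at 62.8 ± 3.24 TPM without and 60.5 ± 2.36 TPM with poly(I:C) (log2 fold change -0.05, SE 0.051, adjusted p = 0.412). The other 8 members of the family lay under the expression limit in the mean of the 4 libraries. Apol9a and Apol9b were under 0.5 TPM in both untreated libraries and reached the limit only through the treated ones. Their rise was thus partly set by the limit, which also bears on the camera result of the family. The same 4 genes rose when p was adjusted over the list alone. The family passed the camera test with a preset correlation (adjusted p = 0.00581), and did not with an estimated correlation (adjusted p = 0.345 with an estimated correlation). Apol genes are similar in sequence, so the split of TPM between close copies such as Apol9a and Apol9b is uncertain.

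**Figure D2:**
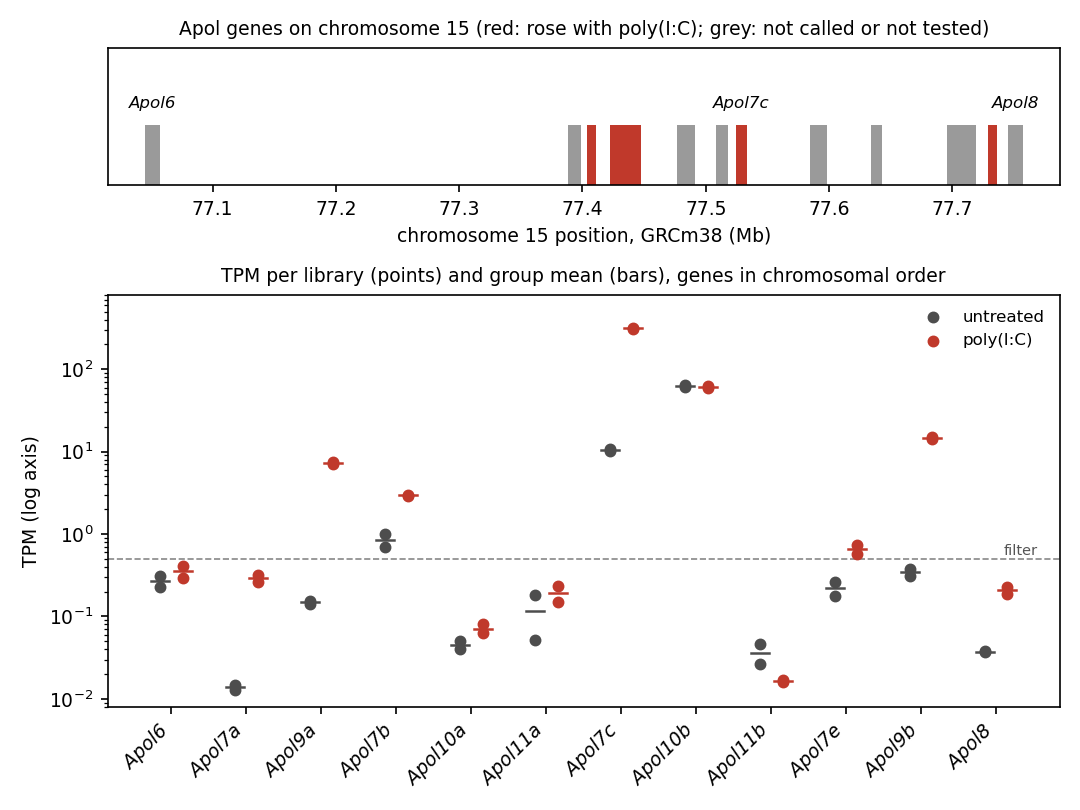
The upper panel maps the 12 Apol genes of chromosome 15 to their GRCm38 positions (Mb), with genes that rose in red and genes not called or not tested in grey. The lower panel gives the TPM of each library (points, log axis) and the group mean (horizontal bars) for untreated (grey) and poly(I:C) (red) cells, with the genes in chromosomal order and the expression limit of 0.5 TPM, set on the mean of all 4 libraries, as a dashed line; Apol7c moves from 10.5 to 313 TPM and Apol10b stays near 60.5 to 62.8 TPM.

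Genes of the antiviral interferon response rose together. All 37 tested interferon-stimulated antiviral genes rose, with a median log2 fold change of 2.87, and 35 of them rose at least 2-fold. Ifit3, an RNA-binding antiviral protein gene, went from 3.49 ± 0.357 to 199 ± 16.2 TPM, and Irf7, a transcription factor that drives interferon genes, from 0.240 ± 0.0110 to 39.5 ± 2.72 TPM. All 15 tested interferon-inducible GTPase genes rose at least 2-fold, led by Tgtp1 (1.57 ± 0.204 to 74.8 ± 2.48 TPM, log2 fold change 4.88) and Gbp2 (3.41 ± 0.0867 to 52.7 ± 1.71 TPM, 3.60). All 37 and all 15 also rose when p was adjusted over each list alone. Both lists passed camera with a preset correlation (adjusted p = 6.12e-22 and 3.39e-09) and neither did with an estimated correlation (adjusted p = 0.345 with an estimated correlation for both). Tgtp1 and the Gbp genes have close copies, which makes their separate values uncertain.

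The interferon genes themselves were near or at 0 at this time. None of the 20 type I, II and III interferon genes in the table reached the expression limit, and 11 were listed at 0 in all 4 libraries. The highest value was that of Ifnb1, at 0.0483 and 0.0420 TPM in the untreated and 0.359 and 0.393 TPM in the treated libraries.

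The list of nucleic acid sensing and adaptor genes moved in both directions. Of 15 tested genes 9 rose, 4 fell and 2 did not pass, with the same counts when adjusted over the list alone. Tlr2 and Tlr4, which rose, and Tlr11 and Tlr12, which fell, are in this list although their known ligands are not nucleic acid. The cytosolic RNA sensor genes Ddx58 (log2 fold change 3.69), Ifih1 (2.89) and Dhx58 (2.64) were in the antiviral list and rose. The genes in these last sentences were named after their values were seen. The kinase gene Ikbke rose from 0.0654 ± 0.000997 to 3.92 ± 0.503 TPM (log2 fold change 2.2) and the adaptor gene Myd88 from 67.0 ± 1.90 to 247 ± 1.52 TPM (1.87). Tlr3, the endosomal receptor for double-stranded RNA, fell from 253 ± 11 to 144 ± 10.7 TPM (log2 fold change -0.81, SE 0.059, adjusted p = 0.000172 in limma). The list as a whole did not pass camera (adjusted p = 0.236 with a preset correlation).

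Cytokine and chemokine genes rose with poly(I:C). Of 13 tested cytokine genes 10 rose and 3 fell, and the largest changes were in the inflammatory cytokine genes Il1b (2.69 ± 0.174 to 105 ± 2.65 TPM, log2 fold change 4.85) and Tnf (4.18 ± 0.0600 to 54.3 ± 1.92 TPM, 3.42). The counts were the same when adjusted over the list alone. Of 14 tested chemokine genes 11 rose, 1 fell and 2 did not pass, and 12 rose and 1 fell when adjusted over the list alone. Besides Ccl5, the largest rise was in Cxcl9, whose product attracts activated T cells (16.7 ± 0.190 to 398 ± 7.52 TPM, 4.49). A chemokine gene that did not pass, Cxcl11, was at 0.00246 TPM in PolyIC01 and 2.78 TPM in PolyIC02, so its value rests on the latter library; it was chosen after its values were seen. In camera with a preset correlation the adjusted p was 0.00355 for cytokines and 3.01e-06 for chemokines. With an estimated correlation both calls were lost (adjusted p = 0.486 and 0.345 with an estimated correlation).

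Genes of dendritic cell maturation and of NF-kB signalling rose without exception among those tested. All 16 maturation genes rose, 12 of them at least 2-fold on the log2(TPM + 1) scale, among them Ccr7, the receptor that guides dendritic cells to lymph nodes (0.161 ± 0.0268 to 25.8 ± 2.87 TPM, log2 fold change 4.52), and the signalling inhibitor gene Socs3 (1.86 ± 0.197 to 19.5 ± 0.850 TPM, 2.84). All 16 NF-kB targets and feedback genes rose, 13 of them at least 2-fold, led by Traf1 (3.49 ± 0.00646 to 96.9 ± 4.25 TPM, 4.44) and Tnip3 (1.2 ± 0.161 to 24.2 ± 0.669 TPM, 3.49). The counts were the same when adjusted over each list alone. Camera with a preset correlation gave adjusted p = 3.39e-09 for maturation and 7.21e-10 for NF-kB, and neither call held with an estimated correlation (adjusted p = 0.345 with an estimated correlation for both).

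Antigen presentation genes of MHC class I rose more uniformly than those of class II, a difference between the lists that was not itself tested. Of 23 MHC class I genes tested, 18 rose, 4 fell and 1 did not pass, with a median log2 fold change of 0.70. Under the alternative settings run per gene 18 to 19 rose, but the number that fell went down to between 1 and 3 under several of them. Nlrc5, the transcriptional activator of class I genes, went from 28.8 ± 2.85 to 117 ± 5.80 TPM (log2 fold change 1.98) and the non-classical class I gene H2-T23 from 190 ± 1.10 to 497 ± 7.51 TPM (1.39). Of 13 MHC class II genes, 6 rose, 4 fell and 3 did not pass. Lgmn, a lysosomal protease gene, rose from 49.4 ± 0.102 to 96.7 ± 8.21 TPM (0.95), while H2-Ob, a subunit of the inhibitor of class II peptide loading, fell from 33.4 ± 0.845 to 12.9 ± 0.312 TPM (-1.30). The falls were not confined to that inhibitor: the other genes that fell were H2-DMb1 (-0.65), H2-DMa (-0.74) and H2-DMb2 (-0.78), named after their values were seen. Counts for both lists were the same when adjusted over each list alone. The class I list passed camera with a preset correlation (adjusted p = 1.75e-06) but not with an estimated one (adjusted p = 0.345 with an estimated correlation), and the class II list did not pass (adjusted p = 0.341 with a preset correlation). Class I genes are similar in sequence, so TPM may be divided unevenly between H2 genes.

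Genes used in cross-presentation, in membrane damage and its repair, and in uptake moved in both directions. Of 25 cross-presentation and phagosome genes 14 rose, 9 fell and 2 did not pass. The largest changes were in Cybb, the catalytic subunit of the phagocyte NADPH oxidase (13.5 ± 0.50 to 75.3 ± 3.40 TPM, log2 fold change 2.40), and Lnpep, an endosomal aminopeptidase gene (18.7 ± 0.459 to 44.2 ± 1.3 TPM, 1.19). Of 16 genes of pore formation, membrane damage and repair 7 rose, 4 fell and 5 did not pass. The galectin genes Lgals9 (47.4 ± 0.824 to 311 ± 1.73 TPM, log2 fold change 2.69) and Lgals8 (10.5 ± 0.729 to 31.7 ± 2.14 TPM, 1.5) led it; galectin-8 binds sugars exposed on ruptured vesicles. Of 15 phagocytic and pattern recognition receptor genes 9 rose, 5 fell and 1 did not pass, with the largest rises in Axl, a receptor for dying cells (27.9 ± 0.607 to 163 ± 2.75 TPM, 2.51), and Clec7a, the beta-glucan receptor (12.1 ± 0.151 to 71.0 ± 1.44 TPM, 2.46). Counts for the 3 lists were the same when adjusted over each list alone. None of the lists passed camera with a preset correlation (adjusted p = 0.0523, 0.0685 and 0.0683 in this order). These values lie near the threshold, and each list passed under some of the alternative settings.

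Genes that mark the cDC1 identity moved in both directions. Of 17 tested, 7 rose, 6 fell and 4 did not pass, and the list did not pass camera (adjusted p = 0.739 with a preset correlation). The number that rose depended on the settings, with 4 without PolyIC01, without PolyIC02 or in limma without trend or robust moderation, while 6 to 7 fell under every setting run per gene. Irf8, the transcription factor that sets up the lineage, was at 2479 ± 3.36 TPM without and 2599 ± 57.6 TPM with poly(I:C), a log2 fold change of 0.07 whose adjusted p of 0.0497 in limma was lost under 6 settings. Its partner Batf3 fell from 144 ± 1.74 to 117 ± 4.0 TPM (log2 fold change -0.30, adjusted p = 0.000772). Clec9a, the receptor for dead-cell actin, was at 198 ± 16.5 and 231 ± 8.23 TPM (0.23, adjusted p = 0.0262), and this call was lost under 5 settings. The largest changes were in Cd24a, which fell from 382 ± 1.72 to 143 ± 2.63 TPM (-1.42), and in the chemokine receptor gene Xcr1, which rose from 192 ± 2.53 to 331 ± 6.38 TPM (0.78). The counts were the same when adjusted over the list alone.

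Markers of other cell types were mostly low, and those that changed did not share a direction. Of 9 tested macrophage and monocyte markers 6 rose, 1 fell and 2 did not pass, the largest rises being in the complement gene C1qb (12.3 ± 0.738 to 125 ± 3.75 TPM, log2 fold change 3.24) and in Ms4a7 (9.73 ± 0.762 to 92.2 ± 3.71 TPM, 3.12). This list passed camera with a preset correlation (adjusted p = 0.00712) and not with an estimated one (adjusted p = 0.345 with an estimated correlation). Of 6 cDC2 markers 2 rose and 2 fell: Cd4 went from 6.27 ± 0.331 to 35.5 ± 0.625 TPM (2.33), and Sirpa was at 0 and 0.365 TPM in the untreated and 1.79 and 2.14 TPM in the treated libraries (1.34). The median (-0.21), the camera direction (down) and the mean (0.19) of this list differ in sign. Of 4 plasmacytoid dendritic cell markers, Pacsin1 rose from 0.360 ± 0.0595 to 3.96 ± 0.0821 TPM (1.87) and Cox6a2 fell from 16.1 ± 0.0199 to 12 ± 0.251 TPM (-0.39); the median of the list was -0.02, its mean 0.36 and its camera direction up. Neither list passed camera (adjusted p = 0.802 for both). Cd3d, 1 of 2 tested T cell markers, rose from 0.842 ± 0.233 to 1.53 ± 0.0861 TPM, a call that was lost without NT02 (adjusted p = 0.0586) and without PolyIC01 (adjusted p = 0.0780). The only tested B cell marker, Ms4a1, rose from 3.38 ± 0.283 to 6.25 ± 0.688 TPM. The epithelial genes Cdh1 (1.23 ± 0.0480 to 0.388 ± 0.0293 TPM) and Epcam (9.71 ± 0.878 to 7.31 ± 0.0852 TPM) fell. In each of these lists the counts were the same when adjusted over the list alone.

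Proliferation genes fell. Of 25 tested, 21 fell, 2 rose and 2 did not pass, with a median log2 fold change of -0.88, and 22 fell and 3 rose when adjusted over the list alone. The mitotic cyclin gene Ccnb2 fell from 143 ± 0.651 to 46.2 ± 0.179 TPM (log2 fold change -1.61) and Birc5, which encodes survivin, from 207 ± 4.39 to 67.2 ± 1.84 TPM (-1.61). The genes that rose were Ccne1 (log2 fold change 0.45) and Mcm6 (0.20), which act at entry into S phase and in replication. Genes of that phase did not rise as a class. Mcm2, Mcm3, Mcm5, Mcm7, Tyms, Tk1, Rrm2 and E2f1 fell, with log2 fold changes from -0.10 (Mcm3) to -1.21 (Rrm2), and Pcna and Mcm4 did not pass. The genes in these sentences on S phase were named after their values were seen. The list passed camera with a preset correlation (adjusted p = 4.20e-07) and not with an estimated one (adjusted p = 0.345 with an estimated correlation).

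Cell death and stress genes rose for the most part. Of 19 cell death genes 16 rose, 1 fell and 2 did not pass, led by the inflammatory caspase gene Casp4 (0.121 ± 0.0317 to 10.9 ± 2.77 TPM, log2 fold change 3.39) and the anti-apoptotic gene Bcl2a1b (147 ± 0.702 to 661 ± 45.6 TPM, 2.16), which has close copies. Members of this list act for and against cell death: Pmaip1 and Bbc3, which promote apoptosis, and Mcl1, which opposes it, rose too, and Bcl2, which opposes it, fell; these 4 were named after their values were seen. Of 12 genes of the unfolded protein response 9 rose and 3 fell, with the largest rises in the stress transcription factor genes Ddit3 (55 ± 6.07 to 185 ± 3.13 TPM, 1.74) and Atf3 (27.5 ± 0.830 to 66.4 ± 0.308 TPM, 1.24). Camera with a preset correlation gave adjusted p = 2.09e-06 and 0.0310, and both calls were lost with an estimated correlation (adjusted p = 0.345 and 0.590 with an estimated correlation). The counts were the same when adjusted over each list alone.

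Of 19 cholesterol synthesis genes 9 rose, 3 fell and 7 did not pass, and Fdft1 was among those that rose (43.8 ± 0.673 to 68.1 ± 0.781 TPM, log2 fold change 0.63). Of 15 glycolysis genes 4 rose and 11 did not pass; the glucose transporter gene Slc2a1 went from 22.2 ± 3.90 to 56.3 ± 0.957 TPM (1.32) and Pfkp from 433 ± 16.3 to 803 ± 9.55 TPM (0.89). Neither list passed camera (adjusted p = 0.133 and 0.462 with a preset correlation), and in glycolysis the median (-0.01) differed in sign from the mean (0.15) and the camera direction (up). Glycolysis depended on the untreated libraries: without NT01 8 genes fell and 4 rose, and without NT02 2 fell and 7 rose. The counts were the same when adjusted over each list alone.

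**Figure D3:**
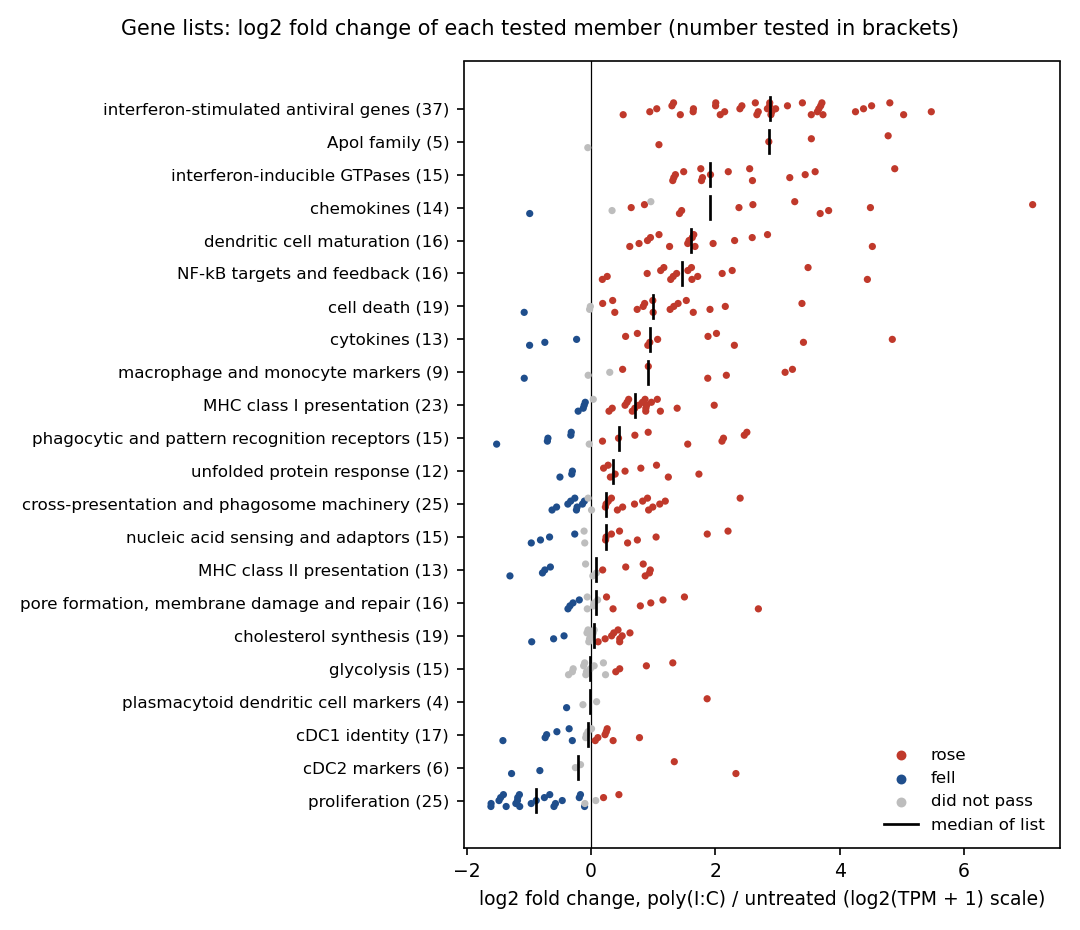
Log2 fold change (horizontal axis, log2(TPM + 1) scale) of each tested member of the gene lists with at least 3 tested members, ordered by median. Each point is a gene, red where it rose, blue where it fell and grey where it did not pass; the black bar is the list's median, which runs from -0.88 for proliferation to 2.87 for interferon-stimulated antiviral genes.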

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

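No paired analysis was possible because the header leaves open which replicate number each column carries, apart from NT01. Counts of genes that rose or fell stayed within 1.5 times under every scaling, pseudocount, expression limit and left-out library tried. With a 2-fold limit they came to 712 and 345 by construction. Among genes that moved at least 2-fold, those that fell numbered 552 and 574 with pseudocounts of 0.1 and 0.01, which shrink low genes less, and per transcript 1479 rose and 755 fell; 99.7% of the 712 and of the 345 were shared with the calls at a pseudocount of 0.1. Without each library in turn, 2722 to 3756 genes rose and 3402 to 3951 fell; a group left with 1 library is then assumed to vary like the other group.

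Apol7c rose under all 14 settings, with a log2 fold change between 3.92 and 6.03, the extremes being its predicted and its curated transcript, and an adjusted p between 1.60e-09 and 0.00514. Of 763 comparisons of other named genes with an alternative, 746 kept their direction and their side of the threshold and 16 lost the call: Irf8 in 6, Clec9a in 5, Cd3d and Snora23 in 2 each and Sirpa in 1 (pseudocount of 0.01, adjusted p = 0.10). Apol10b, which did not pass, changed sign without NT01 (log2 fold change 7.55e-05) and was lowest without NT02 (-0.10). Over the settings run per gene, the members that rose numbered 6 to 9 for nucleic acid sensing, 4 to 7 for cDC1 identity, 0 to 1 for T cell markers and 1 to 2 for cDC2 markers, and those that fell 1 to 4 for MHC class I, 2 to 4 for pore formation and repair, 2 to 3 for cytokines and 1 to 2 for macrophage, plasmacytoid and epithelial markers. With an estimated correlation 0 lists rose and 0 fell by camera, against 11 and 1 with the preset one. List directions that turned were of lists that did not pass: cDC1 identity went up with quantile scaling (adjusted p = 0.94) and per transcript (0.814), cDC2 markers went up per transcript (0.993) and without NT02 (0.807, against 0.907 without PolyIC02), glycolysis went down without NT01 (0.378) and passed upward without NT02 (0.0168, against 0.610 without PolyIC02), nucleic acid sensing went down per transcript (0.993) and plasmacytoid markers went down with no expression limit (0.952). For all of these the cause was not tested. Unknown depth limits what can be said of genes near 0, such as the interferon genes.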

Other observations

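The gene families below were chosen after the genes with the largest changes had been seen, and of the tests in this part, both for the C1q genes, the dilution test for ribosomal protein genes and the stricter count of neighbouring genes were written after the results they measure. In several gene families, a few of whose members are also in the lists, most or all tested members rose, where 28.4% of all tested genes did; no set test was made on these families. All 9 tested Schlafen genes, which include an antisense and a pseudogene symbol, rose at least 2-fold, with Slfn5 going from 14.1 ± 1.14 to 248 ± 19.1 TPM (SD, n = 2 libraries per group throughout) and Slfn2 from 119 ± 3.45 to 723 ± 10 TPM. All 11 tested PYHIN genes, which encode DNA-binding sensors and regulators, rose, 9 of them at least 2-fold; Ifi205 went from 273 ± 4.14 to 1967 ± 80.7 TPM and Aim2 from 72.1 ± 2.45 to 104 ± 3.37 TPM. All 8 tested of 21 Ms4a genes and all 5 tested of 7 Ifitm genes rose. The medians of these families stayed above 0 under every scaling tried. Without an expression limit still 8 Ms4a genes rose, and the median log2 fold change of that family went from 1.97 to 0.73. Some family members passed the limit only through the treated libraries, such as Slfn4 (0.1 ± 0.08 to 5.5 ± 0.07 TPM), so their rise was partly set by the limit. Among 13 PARP genes 8 rose and 3 fell: Parp14 rose from 25.2 ± 2.05 to 168 ± 10.6 TPM, while Parp1, which acts in DNA repair, fell from 115 ± 2.45 to 75 ± 0.228 TPM. Other families were less uniform: of 39 TRIM genes 19 rose, 6 fell and 14 did not pass, with a median log2 fold change of 0.22, and of 4 Ly6 genes 3 rose and 1 did not pass. The TRIM median depended on the settings, from 0.06 with no expression limit to 0.32 with a pseudocount of 0.01. Close copies make separate values in these families uncertain.

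The 3 Rtl8 genes, derived from a retrotransposon and close to each other in sequence, fell together, Rtl8c from 399 ± 0.347 to 82.6 ± 3.61 TPM (log2 fold change -2.26). Of 72 tested nuclear-encoded subunits of oxidative phosphorylation 65 fell and 1 rose, with a median log2 fold change of -0.32, and 1 of them fell at least 2-fold. Among 37 proteasome subunits 21 rose and 6 fell, all by less than 2-fold, with a median of 0.09 that came to 0.01 with quantile scaling. These counts depended on the settings: 19 rose and 1 fell with median-of-ratios scaling, and 14 rose and 7 fell with quantile scaling. No family median changed sign under the settings run per gene; values per transcript were not run for families.

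The complement genes C1qa, C1qb and C1qc and Ms4a7, which macrophages express strongly, rose by 411.9 TPM in sum. Macrophages or monocytes mixed into the treated cultures would bring their other transcripts too, but Csf1r, Adgre1, Vcan and Ly6c2, which the untreated line hardly expresses, rose by only 0.320 TPM in sum, 0.078% of that rise, Lyz2 fell from 218 to 103 TPM and Cd68 was at 252 and 244 TPM. These values argue against such a mixture. That all 4 genes lay higher in both treated libraries restates how they were chosen and bears on no cause, so induction within the cell line was not tested and stays open.

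Ribosomal protein genes fell: 74 of 80 tested, with 1 rising and a median log2 fold change of -0.45 (SE 0.027 across genes). Genes that rose at least 2-fold take a larger share of a fixed total, from 2.75% to 9.15% of the matched TPM, yet this dilutes all other genes by only -0.098 on the log2 scale. Smaller rises were not counted, among them those of abundant genes such as B2m (2449 to 4510 TPM). The dilution by all risen genes is therefore larger, and it was not computed. A shift shared by most genes would be largely removed by rescaling. The ribosomal protein median was still -0.417 with median-of-ratios scaling, where 70 genes fell, and -0.355 with quantile scaling, where 74 fell. Short transcripts as a class did not fall as far: 356 other abundant genes with short transcripts had a median of -0.172 (SE 0.049 across genes). Both SEs treat genes of the same libraries as independent, which they are not, and measure no spread between libraries. The dilution of -0.098 argues against genes that rose at least 2-fold as the whole cause. The rescaled medians argue against a dilution shared by most genes as the whole cause, and the median of -0.172 against short transcripts as the whole cause. A lower supply of ribosomes in the treated cells was not tested, and without depth the total RNA per cell stays open.

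Neighbours were taken among the 12517 tested genes with a chromosome position, and untested genes lying between them were skipped. In this order genes that rose at least 2-fold lay next to one another 169 times along the chromosomes, against a mean of 40.4 and a highest value of 65 in 10000 shuffles of the calls (permutation p = 0.0001, the smallest these shuffles can give), which argues against chance order. The longest runs were 11 genes at the Schlafen cluster of chromosome 11 and 9 genes at the PYHIN cluster of chromosome 1. Reads shared between paralogs could add such pairs. Without pairs that share a symbol stem, the test set beforehand, 98 pairs were left against a highest shuffled value of 62, but 55 of them hold a predicted, clone, antisense or pseudogene name, whose stem cannot show a paralog; without these, 43 pairs were left, above the shuffled mean of 29.8 (permutation p = 0.01) but below the highest of 51, so shared reads and clustered induction cannot be told apart.

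Cdkn1a, a cell cycle inhibitor gene that p53 can activate, rose from 62.0 ± 2.32 to 629 ± 3.19 TPM, chosen after its value was seen. If p53 were active, at least 75% of other p53 target genes were predicted to rise, and under 50% if not. Genes whose values had already been seen were left out of this list. Pmaip1, Bbc3 and Bax, which p53 can also activate, are not in it and rose, so the share is not that of all p53 targets. Of 18 listed genes tested 12 rose (66.7%) and 0 fell, against 28.4% of all tested genes that rose. This lies between the 2 predictions, so the test does not decide whether p53 was active. Nor can it tell p53 from other signals that raise the same genes.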
